A study of Mus musculus with 12 samples.

How the data were processed

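Bulk RNA sequencing of mouse haematopoietic stem and progenitor cells was analysed for 12 libraries in 4 groups of 3, assigned from the sample titles: young uncultured, aged uncultured, aged cultured with vehicle and aged cultured with uridine. RNA was extracted with Trizol, messenger RNA was purified with poly-T beads, and libraries were sequenced as paired reads of 150 bp on a NovaSeq instrument, per the labels' protocols. Reads were aligned with HISAT2 2.0.5 to mm10, per the submitters' processing notes. The values analysed were raw read counts per gene, deposited by the authors as a table of 54532 Ensembl gene IDs. The counting program, its annotation and its use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The surface markers of the sort, the culture time and the uridine dose are likewise not given in the sources used here.

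Gene symbols, biotypes and positions came from GENCODE M21. The deposited count table had no biotype of its own for this purpose. Of the IDs 54409 were matched and 123 were not, and the latter held at most 0.0649% of any library's counts and stayed in the tests. Library totals ran from 16785065 to 19025802 counts, so that a gene with 0 counts in a group of 3 libraries could be bounded at 3 counts over the group with 95% confidence. No value column of the table was left unused.

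Genes were kept by edgeR's filterByExpr on the 4 groups, which left 16675. TMM factors were computed, a model with 1 mean per group was fitted to all 12 libraries with the edgeR 4.0.16 quasi-likelihood method (residual degrees of freedom 8, prior degrees of freedom 26.47), and contrasts were tested with the quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The contrasts were aged against young uncultured cells, uridine against vehicle cultures, and vehicle cultures against uncultured aged cells. Gene lists fixed by hand were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 39 lists that had enough measured genes, and list members were also adjusted over their list alone. The genes higher or lower with age were tested as sets in the uridine contrast, and their overlap was tested with Fisher's exact test, two-sided. Ratios of genes with 1 to 3 counts in the lower group carry a counting interval at 95% confidence. Replicate pairs were compared by a chi-square test on genes with at least 50 counts in the pair. The groups, contrasts, tests, filters, gene lists and most alternatives were chosen before the data were examined.

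Named genes followed a rule of that time. They were protein-coding genes with a symbol (no predicted genes, pseudogenes or antigen receptor segments) at an adjusted p under 0.05, a mean of at least 5 CPM over the 6 libraries and no overlap between groups, of which the 10 largest changes in each direction were eligible. For each list, up to 4 called members with the smallest p were eligible, or the 2 most abundant where none was called. For the overlap of age and uridine, up to 10 genes of opposite and 10 of the same sign were eligible, ranked by the larger adjusted p. Any member of the lists of stem cell ageing, pyrimidine metabolism, nucleoside transporters and sex-linked genes could be named besides. Genes of plasma cells were chosen after their values were seen.

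The position of the uridine libraries between the vehicle and young libraries was measured on genes at least 10 times higher in young than in vehicle libraries, with at least 5 CPM in young libraries and a floor of 0.05 CPM in the ratio. The fraction was the uridine level less the vehicle level, divided by the young level less the vehicle level, and genes within 0.1 of the median fraction were counted. This measure was chosen after seeing the data.

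Alternatives to the main choices were DESeq2 1.42.0, limma voom, other scaling factors (the DESeq2 size factors and the upper quartile), no low-count filter, a filter of 1 CPM in 3 libraries, a fit of the 6 compared libraries only, the replicate number as a block, protein-coding genes only, a log2 threshold of 1, camera with an estimated correlation, fry, an adjusted p of 0.01 for the age sets, and leaving out each library in turn. After seeing the data, 3 were added: leaving out immunoglobulin genes and Jchain before scaling, asking for a call in the same direction against young cells as well, and subtracting the young-like fraction from the uridine libraries.

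The analysis was tested on simulated data with 50 genes changed at each of 4 fold sizes, per contrast. For aged against young cells (16137 simulated genes tested), 46, 52, 80 and 98% of the genes changed by 1.25, 1.5, 2 and 4 times were recovered, and 8.61% of calls were false. For uridine against vehicle (16146 genes) the values were 48, 80, 78 and 94%, with 7.98% of calls false, and for vehicle against uncultured aged cells (16111 genes) 50, 70, 74 and 98%, with 6.41% of calls false. Of 100 unchanged lists of 20 genes, 0 were called in any contrast. Genes were simulated independently of each other, so this does not test lists of genes that vary together. Far fewer genes were changed than were called in the real contrasts. True mixing fractions of 0.1, 0.2, 0.3 and 0.5 were estimated as 0.0998, 0.198, 0.299 and 0.502. The software was R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.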

Results

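Messenger RNA was sequenced from haematopoietic stem and progenitor cells (HSPCs), the bone marrow cells from which the blood lineages arise, of wild-type mice. The genotype labels run from C57BL/6 to C57BL/15 across the samples, a sequence that may be a spreadsheet fill, so the strain is uncertain. The 12 libraries formed 4 groups of 3: uncultured cells of young mice, uncultured cells of aged mice, aged cells cultured with vehicle, and aged cells cultured with uridine. Uridine is a pyrimidine nucleoside that cells take up and phosphorylate to UMP. The deposited gene counts totalled 16785065 to 19025802 per library, and 16675 genes passed the low-count filter. Levels are given as CPM, counts scaled to library size with TMM factors, as the mean ± SD of 3 libraries. Gene positions refer to the GRCm38 assembly, which is the mm10 build, with GENCODE M21 gene models.

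The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. Libraries of the same group were close to each other, but each of the 12 within-group pairs differed by more than sampling noise, with chi-square values of 2.27 to 3.94 per degree of freedom. The common biological coefficient of variation was 0.0438, and small differences were therefore called.

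Immunoglobulin genes set the uncultured aged libraries apart from the others. They held 19.8% ± 0.167 of all counts there (SD, n = 3), against 0.510% ± 0.00259 in uncultured young cells, 0.841% ± 0.00166 in vehicle cultures and 0.560% ± 0.00663 in uridine cultures. The 10 most abundant genes took 20.7% of the counts in uncultured aged cells and 4.23% in young cells. Jchain, which joins the chains of secreted IgA and IgM, alone took 1.96% ± 0.0104 of the counts in uncultured aged cells and 0.0321% ± 2.30e-05 in young cells.

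**Figure D1:**
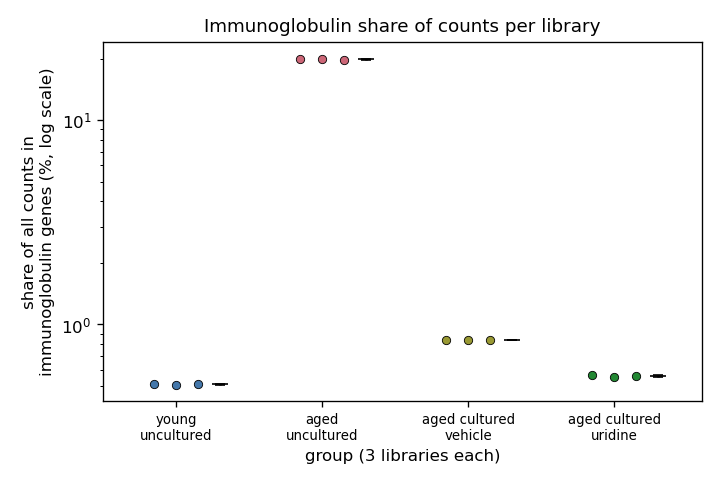
Share of each library's counts (percent, log axis) that fell in immunoglobulin genes, with the 3 libraries of each group as points and the group mean ± SD as a bar. Uncultured aged libraries lay at 19.63% to 19.96%, and the other 9 libraries lay at 0.507% to 0.842%.

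The comparison of uncultured aged with uncultured young HSPCs asked how the cells differ with the age of the mouse. Genes of maturing neutrophils, of erythroid cells, of basophils and mast cells and of the cell cycle were lower in aged cells, whereas most genes of B cells (11 of 16) and of the unfolded protein response (14 of 20) were higher. Ltf, which encodes lactoferrin of neutrophil granules, was at 1024 ± 8.17 CPM in young and 57.3 ± 1.97 CPM in aged cells. Jchain stood at 303 ± 0.291 CPM in young and 23470 ± 124 CPM in aged cells. Mki67, a marker of proliferating cells, was at 1195 ± 11.7 and 367 ± 15.6 CPM. In all, 5535 genes were higher and 5354 lower in aged cells at an adjusted p under 0.05 by edgeR's quasi-likelihood test (65.3% of those tested), of which 2105 and 1508 changed by at least 1 on the log2 scale. The libraries of both groups did not overlap for 11159 genes (66.9%), where chance gives 10%.

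Of the 39 fixed gene lists tested in this comparison, camera (limma) called 6 higher and 9 lower in aged cells. With an estimated correlation the smallest limma camera adjusted p of any list was 4.09e-06, so smaller values here rest on the preset correlation. All 15 measured genes of mature neutrophils fell, with a median log2 fold change of -3.20 (limma camera adjusted p = 7.90e-60). Ltf (log2 fold change -4.16, SE 0.0380, edgeR adjusted p = 1.43e-42) was joined by Ngp, another granule protein, which went from 1602 ± 34.0 to 122.5 ± 2.02 CPM. Chil3 and S100a9, both abundant in maturing neutrophils, fell by 3.13 and 2.67 on the log2 scale. Among 20 erythroid genes 19 fell and 1 was not called (median -1.41, limma camera adjusted p = 3.39e-09). Slc4a1, the anion exchanger of red cells, went from 68.9 ± 2.54 to 5.48 ± 0.591 CPM, and Tfrc, the transferrin receptor, from 316 ± 2.44 to 132 ± 5.28 CPM. Basophil, mast cell and eosinophil genes gave 13 that fell and 2 not called of 15 (median -1.38, limma camera adjusted p = 1.79e-10). The basophil proteases Prss34 (689.6 ± 15.8 to 72.3 ± 3.52 CPM) and Mcpt8 (196 ± 6.79 to 46.3 ± 0.405 CPM) were among them. Genes of monocytes and macrophages were divided, with 13 lower, 5 higher and 3 not called (median -0.77, limma camera adjusted p = 3.16e-05). Lyz2, the lysozyme of myeloid cells, went from 995 ± 34.7 to 140.0 ± 2.18 CPM, while Ctss, a lysosomal protease, rose by 1.57 on the log2 scale.

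Every measured gene of S phase (28 of 28, median -0.82) and of the G2 and M phases (25 of 25, median -0.87) was lower in aged cells. The limma camera adjusted p-values were 9.05e-14 and 7.47e-15. Uhrf1, which maintains DNA methylation during replication, was at 450.4 ± 6.70 CPM in young and 162 ± 4.97 CPM in aged cells. The replication helicase subunits Mcm2 and Mcm5 fell by 1.04 and 0.96 on the log2 scale, and the topoisomerase Top2a fell by 1.08.

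B lineage genes moved both ways, with 11 higher and 5 lower in aged cells (median 1.62, mean 0.82, limma camera adjusted p = 2.34e-23). Genes of mature B cells were among those that rose, such as Cd74, the invariant chain of MHC class II (245 ± 4.48 to 4113 ± 112 CPM), and Cd79a of the B cell receptor (134 ± 2.91 to 698 ± 24.6 CPM). Igll1, a part of the receptor of B cell precursors, fell from 111 ± 1.86 to 4.04 ± 1.16 CPM. Jchain (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891, minus strand) had the smallest edgeR adjusted p of the named genes, 1.58e-58, at a log2 fold change of 6.28 (SE 0.0186). The share of counts in immunoglobulin genes given above rose in the same libraries. Of 17 genes of T and natural killer cells 12 rose, 2 fell and 3 were not called (median 1.03, limma camera adjusted p = 0.0209). That call was lost at adjusted p = 0.0666 with an estimated correlation. Cd2, an adhesion receptor of T cells, went from 4.35 ± 1.09 to 66.4 ± 2.09 CPM, and Cd8a rose by 2.72 on the log2 scale.

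Of 20 genes of the unfolded protein response 14 rose, 5 fell and 1 was not called (median 0.52, limma camera adjusted p = 6.45e-06). Xbp1, a transcription factor of this response that plasma cells also need, went from 184 ± 5.02 to 858 ± 5.04 CPM, and Herpud1 rose by 1.90 on the log2 scale, whereas the chaperone Hspa5 fell by 0.54. Among 15 genes of granulocyte progenitors 10 rose, 2 fell and 3 were not called (median 0.27, limma camera adjusted p = 3.60e-04). The protease genes Elane (1386 ± 13.8 to 2795 ± 72.7 CPM) and Prtn3 (1325 ± 27.4 to 2425 ± 36.3 CPM) were higher in aged cells, in contrast to the genes of mature neutrophils. Immediate early genes, which cells switch on within minutes of a stimulus, gave 14 that rose, 8 that fell and 1 not called (median 0.36, limma camera adjusted p = 0.00907). Their call was lost at adjusted p = 0.119 with an estimated correlation. Junb rose by 1.30 on the log2 scale (SE 0.0251, edgeR adjusted p = 3.06e-32), and Klf6 fell by 0.94.

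Genes known to be higher in stem cells of old mice were mostly higher here: 25 of 33 measured rose, 6 fell and 2 were not called (median 1.46, limma camera adjusted p = 0.00874). This list was not called at adjusted p = 0.0602 with an estimated correlation. Selp (P-selectin, 6.20 ± 0.557 to 22.1 ± 2.34 CPM), Ehd3 (5.25 ± 0.600 to 22.9 ± 2.21 CPM), Slamf1 (1.06 ± 0.129 to 6.88 ± 0.255 CPM) and Cd38 (5.03 ± 0.870 to 66.3 ± 2.15 CPM) were among those that rose. Vwf and Itgb3, which megakaryocytes also express, fell by 0.34 and 0.36 on the log2 scale, and Fyb fell by 1.35. Of 24 genes characteristic of stem cells 12 rose, 5 fell and 7 were not called, and the list as a whole was not called (median 0.18, limma camera adjusted p = 0.210). Ly6a, the Sca-1 antigen, went from 17.8 ± 0.986 to 247 ± 4.80 CPM and Procr, the endothelial protein C receptor, from 2.88 ± 0.190 to 15.5 ± 2.63 CPM, while Gata2 fell by 0.73 on the log2 scale.

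Of 12 measured genes of marrow stroma and endothelium 7 fell, 3 rose and 2 were not called (median -2.15, limma camera adjusted p = 1.23e-04). The median ran from -3.33 to -1.71 with single libraries left out, with the call kept. Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042, plus strand), went from 272 ± 8.95 CPM in young to 0.960 ± 0.201 CPM in aged cells (log2 fold change -8.14, SE 0.0850, edgeR adjusted p = 9.94e-41). Col1a2 and Sparc fell by 6.37 and 4.09, and Apoe rose by 1.55. The epigenetic regulators gave 17 lower, 4 higher and 1 not called (median -0.30, limma camera adjusted p = 0.0156; adjusted p = 0.0772 with an estimated correlation), including the maintenance DNA methyltransferase Dnmt1 and the histone methyltransferase Ezh2, which fell by 1.03 and 1.09. Purine synthesis genes gave 15 lower, 2 higher and 2 not called (median -0.31, limma camera adjusted p = 0.0397; adjusted p = 0.119 with an estimated correlation and 0.0540 in a fit of these 6 libraries only). Paics and Pfas of the de novo pathway fell by 0.50 and 0.75.

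Pyrimidine metabolism, the pathway uridine feeds into, was not called as a whole with age (9 of 29 rose, 10 fell and 10 were not called; median 0.01, mean 0.14, test direction down, limma camera adjusted p = 0.451). Cad, which starts de novo synthesis, went from 338 ± 3.52 to 202 ± 2.98 CPM and the ribonucleotide reductase subunit Rrm1 from 449.6 ± 5.19 to 237 ± 4.70 CPM. The ectonucleotidases Nt5e and Entpd1 rose by 3.07 and 1.88 on the log2 scale. Of 5 measured nucleoside transporters 2 rose, 2 fell and 1 was not called (median 0.24, mean 0.21, test direction down, limma camera adjusted p = 0.751). Slc29a1, an equilibrative transporter, went from 106 ± 5.67 to 52.4 ± 4.31 CPM, and the concentrative transporter Slc28a2 from 81.2 ± 3.11 to 144 ± 7.53 CPM. Slc29a4, with 21 counts over the young libraries, rose by 1.60 (edgeR adjusted p = 0.0101), but its edgeR adjusted p was 0.0669 without aged replicate 2 and 0.0833 without young replicate 2. Interferon-stimulated genes (19 fell, 4 rose and 7 were not called; limma camera adjusted p = 0.0676) and the subunits of oxidative phosphorylation (37 rose, 6 fell and 27 were not called; limma camera adjusted p = 0.243) were not called as lists. Adjusted over the list alone, member counts of the lists described for this comparison equalled those over all genes tested.

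Among the genes with the largest change, Gnb3, a G protein subunit, had 2 counts over the young libraries, and its ratio of aged to young was 512 (counting interval 141 to 4236). Such intervals, and the floors used below, cover only the error of independent counting. It lies on chromosome 6 (ENSMUSG00000023439, 124834240 to 124840275, minus strand). Bmp6 (0.105 ± 0.0478 to 12.6 ± 0.640 CPM), Nuggc (0.394 ± 0.352 to 37.2 ± 3.19 CPM) and Zbtb32 (0.875 ± 0.429 to 42.5 ± 2.38 CPM) followed among the genes that rose. Xist, the RNA of the inactive X chromosome and the only measured sex-linked gene of the list, went from 1666 ± 34.8 to 829.8 ± 31.2 CPM, so cells of female mice were present in both groups. Enpep, Retnlg and Gfra2 fell by 6.30, 5.37 and 4.91 on the log2 scale.

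**Figure D2:**
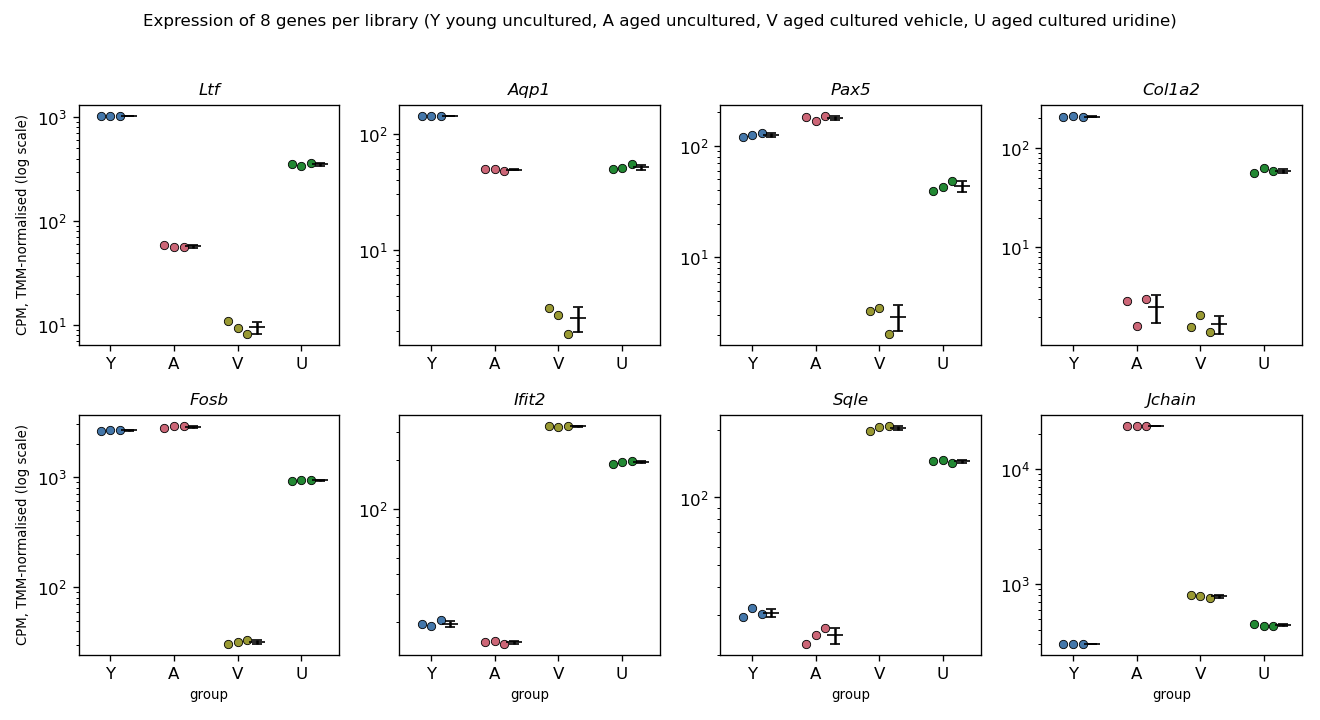
Levels of Ltf, Aqp1, Pax5, Col1a2, Fosb, Ifit2, Sqle and Jchain in the 12 libraries (TMM-normalised CPM, log axis), with libraries as points and the group mean ± SD as bars. Ltf averaged 1024 CPM in young, 57.3 CPM in aged, 9.53 CPM in vehicle and 351 CPM in uridine libraries.

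The comparison of aged HSPCs cultured with uridine against vehicle asked what uridine changes in aged cells, in a series whose title names uridine an anti-aging factor. Uridine cultures had higher levels of immediate early genes and of most genes that mark neutrophils, erythroid cells, B cells and stroma. Interferon-stimulated, cholesterol synthesis and megakaryocyte genes were lower by a smaller margin. Fosb, an AP-1 transcription factor, was at 32.1 ± 1.35 CPM with vehicle and 933 ± 10.8 CPM with uridine. Ltf was at 9.53 ± 1.30 and 351 ± 12.4 CPM, and Ifit2, an interferon-induced gene, at 325 ± 3.43 and 195 ± 3.43 CPM. edgeR called 3342 genes higher and 3018 lower with uridine (38.1% of those tested), and 1054 and 118 of them changed by at least 1 on the log2 scale. The libraries of both groups did not overlap for 8334 genes (49.98%), where chance gives 10%.

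Camera (limma) called 12 of the 39 lists higher and 11 lower with uridine. The smallest limma camera adjusted p of any list was 1.46e-07 with an estimated correlation, so smaller values here rest on the preset correlation. Of 23 immediate early genes 21 rose, 1 fell and 1 was not called (median 1.62, limma camera adjusted p = 3.66e-260; 2 fell when adjusted over the list alone). Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051, minus strand) rose by 4.86 (SE 0.0270, edgeR adjusted p = 1.15e-48), Nr4a1 by 4.48, Fos by 2.96 and Jun by 2.90 on the log2 scale. Targets of the ERK kinase pathway gave 12 that rose, 4 that fell and 6 not called of 22 (median 0.57, limma camera adjusted p = 8.76e-16), led by the phosphatase Dusp1 (log2 fold change 2.29) and the early response factor Egr1 (54.4 ± 2.50 to 224 ± 5.56 CPM).

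Of 15 mature neutrophil genes 13 rose and 2 fell (median 2.27, limma camera adjusted p = 9.25e-156). Ngp (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012, plus strand) went from 31.9 ± 2.45 to 560.4 ± 6.08 CPM and Camp from 6.39 ± 0.589 to 159 ± 0.783 CPM. Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767, plus strand) rose by 5.20 on the log2 scale (SE 0.0486, edgeR adjusted p = 1.82e-41). Among 20 erythroid genes 18 rose and 2 were not called (median 3.91, limma camera adjusted p = 1.67e-53; 19 rose when adjusted over the list alone). Slc4a1 (ENSMUSG00000006574, chromosome 11, 102348824 to 102366203, minus strand) had 0 counts in the vehicle libraries and 24.2 ± 1.27 CPM with uridine, at least 443-fold higher against a floor of 3 counts over the group. Ermap, with 2 counts over the vehicle libraries, had a ratio of 784 (counting interval 217 to 6476). Aqp1, a water channel of red cells, went from 2.57 ± 0.638 to 51.5 ± 2.44 CPM and Car1, a carbonic anhydrase, from 0.165 ± 0.0574 to 40.4 ± 1.03 CPM.

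Of 16 B lineage genes 13 rose, 2 fell and 1 was not called (median 1.73, limma camera adjusted p = 1.69e-35). Pax5, which commits cells to the B lineage, went from 2.92 ± 0.773 to 43.2 ± 4.71 CPM. Jchain moved the other way, from 781 ± 18.1 to 439 ± 9.91 CPM, as did the share of counts in immunoglobulin genes. Of 12 genes of stroma and endothelium 9 rose, 2 fell and 1 was not called (median 2.82, or 2.48 with genes near 0 counts at their bounds; limma camera adjusted p = 6.97e-18). Col1a1 went from 0.236 ± 0.0577 to 76.7 ± 2.72 CPM and Col1a2 from 1.69 ± 0.352 to 59.1 ± 3.13 CPM. Granulocyte progenitor genes (9 rose, 4 fell and 2 were not called; median 0.22, limma camera adjusted p = 6.59e-04) included Mpo, myeloperoxidase, at 2171 ± 45.8 CPM with vehicle and 3544 ± 16.3 CPM with uridine. Lymphoid-primed progenitor genes gave 9 that rose, 5 that fell and 2 not called (median 0.22, limma camera adjusted p = 8.51e-06), led by Dntt, a polymerase of antigen receptor joining (log2 fold change 2.27, edgeR adjusted p = 9.38e-30). Basophil, mast cell and eosinophil genes were divided (6 rose, 4 fell and 5 were not called), with a median of 0.14 (0.07 to 0.16 with single libraries left out) and a mean of -0.0151. The limma camera test called them up (adjusted p = 4.97e-05), but not without the low-count filter (limma camera adjusted p = 0.0670). Prss34 rose from 109 ± 6.15 to 286 ± 4.82 CPM, and the granzyme Gzmb fell from 25.8 ± 0.596 to 11.1 ± 1.26 CPM.

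The rise of these unrelated marker groups had nearly the same size when set against uncultured young cells. For 145 genes at least 10 times higher in young than in vehicle libraries, the uridine level lay at a median of 0.333 of the way from the vehicle to the young level (quartiles 0.310 and 0.363), and 93.1% of them lay within 0.1 of that median. Uncultured aged cells spread widely over the same genes, with 23.4% within 0.1 of their median. The median fraction was 0.337 for 9 neutrophil genes, 0.335 for 8 B lineage genes, 0.332 for 13 erythroid genes, 0.309 for 9 immediate early genes and 0.279 for 3 stroma genes. Over the 3 uridine libraries, the median fraction was 0.337, 0.329 and 0.342. Of the genes called between uridine and vehicle, 5453 (85.7%) had a uridine level between the vehicle and young means, and 134 higher and 196 lower genes were called in the same direction against young cells as well. By log2 0.5 or more against both, 13 were higher and 24 lower. Many of the 196 lower genes encode ribosomal proteins. Levels outside both groups are not what a mixture of them gives, and their cause was not tested.

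**Figure D3:**
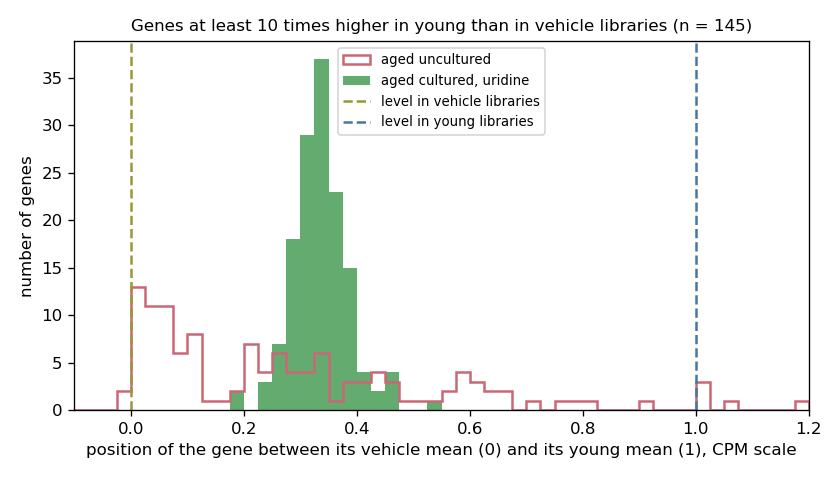
Histogram of 145 genes at least 10 times higher in uncultured young than in vehicle libraries, by where their level in uridine libraries and in uncultured aged libraries lay between the vehicle mean (0) and the young mean (1). Uridine values gathered around a median of 0.333, whereas the uncultured aged values spread, with 19 genes above the plotted range of -0.1 to 1.2.

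All 30 interferon-stimulated genes measured fell with uridine (median -0.72, limma camera adjusted p = 2.52e-54). Ifit2 (ENSMUSG00000045932, chromosome 19, 34550694 to 34576419, plus strand) was joined by Ifitm3 (839 ± 5.74 to 483 ± 3.96 CPM), Isg15 (219 ± 1.85 to 120.2 ± 3.68 CPM) and Irf7 (log2 fold change -0.76). The largest edgeR adjusted p among these 4 genes was 8.36e-20 (Irf7). Of 22 genes of cholesterol synthesis 21 fell and 1 was not called (median -0.47, limma camera adjusted p = 9.10e-13). Sqle, squalene epoxidase, went from 204 ± 5.08 to 145 ± 1.91 CPM, and Cyp51 and Hmgcs1 fell by 0.57 and 0.46 on the log2 scale. Megakaryocyte and platelet genes gave 17 lower and 1 not called (median -0.51, limma camera adjusted p = 1.24e-10), among them Pf4, platelet factor 4 (337 ± 5.64 to 191 ± 5.80 CPM), and the integrin Itga2b (438 ± 6.30 to 319 ± 7.65 CPM). Monocyte and macrophage genes were divided, with 12 lower, 6 higher and 3 not called (median -0.29, limma camera adjusted p = 2.53e-04). Lyz2 and Ctss fell by 0.63 and 0.92, while Irf8, a transcription factor of monocyte and dendritic cell development, rose by 0.55.

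Genes known to be higher in stem cells of old mice gave 14 that fell, 5 that rose and 14 not called with uridine (median -0.35, limma camera adjusted p = 0.00472; adjusted p = 0.0505 with an estimated correlation). Vwf (192 ± 6.70 to 138 ± 4.04 CPM), Selp (53.1 ± 2.42 to 38.4 ± 1.57 CPM), Clu (21.9 ± 0.922 to 15.0 ± 0.800 CPM) and Slamf1 (5.60 ± 0.292 to 3.32 ± 0.439 CPM) were among those that fell. Gpr183 and Mt1 each rose by 0.59. The fall of this list was gone once the young-like fraction was subtracted, as given below. Stem cell genes gave 11 lower, 2 higher and 11 not called (median -0.23, limma camera adjusted p = 0.0135; adjusted p = 0.150 with an estimated correlation), with Ly6a at 455 ± 12.8 and 258 ± 7.76 CPM and Procr at 18.2 ± 0.211 and 10.0 ± 0.913 CPM.

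Several metabolic and stress lists shifted by less. Antioxidant genes gave 17 lower, 3 higher and 5 not called (median -0.13, limma camera adjusted p = 2.36e-04; 4 rose when adjusted over the list alone), including the peroxiredoxin Prdx1 and haem oxygenase Hmox1, which fell by 0.47 and 0.73. Lysosome and autophagy genes gave 12 lower, 4 higher and 10 not called (median -0.13, limma camera adjusted p = 6.59e-04; 14 fell when adjusted over the list alone), with the cathepsins Ctsb and Ctsd lower (log2 fold changes -0.66 and -0.62). Of 70 measured subunits of oxidative phosphorylation 35 fell, 3 rose and 32 were not called (median -0.14, limma camera adjusted p = 0.00123; 39 fell when adjusted over the list alone), a call that was lost at adjusted p = 0.158 with an estimated correlation. Fatty acid genes gave 9 lower and 10 not called (median -0.13, limma camera adjusted p = 0.0217; 12 fell and 1 rose when adjusted over the list alone; adjusted p = 0.0524 with an estimated correlation). Genes of the integrated stress response gave 15 lower, 1 higher and 10 not called (median -0.22, limma camera adjusted p = 0.00852; 2 rose when adjusted over the list alone), such as the cystine transporter Slc7a11 at 44.7 ± 0.760 and 29.8 ± 3.08 CPM. S phase genes were slightly higher, with 17 that rose and 11 not called (median 0.14, limma camera adjusted p = 0.00984; adjusted p = 0.0612 with an estimated correlation). Mcm5 rose by 0.35, and Mki67, of the G2 and M list that was not called (8 of 25 rose, or 7 when adjusted over the list alone; limma camera adjusted p = 0.173), rose by 0.46. Epigenetic regulators gave 12 higher, 4 lower and 6 not called (median 0.18, limma camera adjusted p = 0.00167), with the demethylase Kdm6b higher by 1.52. Histone genes, most of whose transcripts lack poly(A) and which are near-identical to each other, gave 9 higher, 1 lower and 4 not called (median 1.18, limma camera adjusted p = 0.00114) and are uncertain.

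Most of these list medians shrank or changed sign with the young-like fraction of 0.333 subtracted from the uridine libraries, an alternative chosen after seeing the data. It used log2(CPM + 0.5) of list genes with a mean of at least 5 CPM and set negative levels to 0, so a sign change can be an overshoot and was not tested. The genes that set the fraction included 9 neutrophil, 13 erythroid, 8 B lineage and 9 immediate early genes. The loss of the rise in these lists therefore follows in part from how the fraction was set. Among lists that were higher with uridine, the median went from 2.13 to -0.01 for mature neutrophil, 3.16 to -0.10 for erythroid, 1.49 to -0.52 for B lineage, 2.97 to -0.26 for stroma, 1.62 to -0.08 for immediate early and 0.77 to 0.07 for ERK target genes. It went from 0.22 to -0.06 for granulocyte progenitor, 0.11 to -0.24 for lymphoid-primed progenitor, 0.14 to -0.19 for basophil, mast cell and eosinophil, 0.14 to 0.02 for S phase and 0.18 to 0.07 for epigenetic genes. Among lists that were lower, it went from -0.71 to -0.19 for interferon-stimulated, -0.48 to 0.0022 for cholesterol synthesis, -0.49 to -0.04 for megakaryocyte, -0.42 to -0.12 for monocyte, -0.46 to 0.01 for stem cell ageing and -0.20 to -0.05 for stem cell genes. Integrated stress genes went from -0.22 to -0.05, fatty acid genes from -0.11 to 0.05 and lysosome and autophagy genes from -0.13 to -0.12, while antioxidant genes went from -0.13 to -0.16 and oxidative phosphorylation from -0.13 to -0.19.

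Pyrimidine metabolism was not called with uridine: 6 of 29 genes rose, 5 fell and 18 were not called (median -2.17e-03, mean 0.05, limma camera adjusted p = 0.516). Cad went from 241 ± 1.62 to 298 ± 8.38 CPM, and the uridine-cytidine kinases Uck1 (log2 fold change 0.33) and Uck2 (232 ± 2.87 to 262 ± 4.24 CPM), which phosphorylate uridine, rose as well. The largest edgeR adjusted p among these 3 genes was 2.10e-05 (Uck1). Upp1, uridine phosphorylase, went from 7.82 ± 1.15 to 3.96 ± 0.402 CPM (edgeR adjusted p = 6.38e-04). The interferon-inducible Cmpk2 and the dNTP hydrolase Samhd1 fell by 0.52 and 0.42. Umps, which makes UMP de novo, was at 113 ± 0.673 and 114 ± 4.61 CPM and was not called (edgeR adjusted p = 0.974). Of 5 nucleoside transporters 2 rose and 3 were not called (median 0.17, limma camera adjusted p = 0.678): Slc29a1 went from 64.3 ± 1.51 to 76.0 ± 1.57 CPM and Slc28a2 from 61.4 ± 3.05 to 68.9 ± 1.98 CPM. The uridine levels of Slc29a1, Slc28a2 and Cad lay between the vehicle level and the young level given above, as in a mixture. With the young-like fraction subtracted, the median of 25 pyrimidine genes went from -1.97e-03 to -0.08. The Slc28a2 call (edgeR adjusted p = 0.00593) was lost without vehicle replicate 1, at an edgeR adjusted p of 0.0715. Inflammation genes (8 rose, 13 fell and 5 were not called; 14 fell when adjusted over the list alone) had a median of -0.20, a mean of 0.02 and a test direction up, and were not called (limma camera adjusted p = 0.170). Genes of T and natural killer cells (12 rose, 2 fell and 3 were not called; median 1.07) were not called, at a limma camera adjusted p of 0.0546. For the lists described above for this comparison without such a count, member counts adjusted over the list alone were the same.

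Of the genes with the largest change, Hba-a1 and Hbb-bs of haemoglobin share reads with near-identical copies and are uncertain. Mmp9, a granule protease of neutrophils, rose by 6.70 on the log2 scale, and Retnlg, with 3 counts over the vehicle libraries, had a ratio of 352 (counting interval 120.3 to 1711). On the other side, Ceacam19, Slc6a12 and Gzmc fell by 1.39, 1.37 and 1.33 on the log2 scale, and the aminopeptidase Anpep went from 99.4 ± 4.98 to 46.2 ± 2.30 CPM.

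The comparison of vehicle-cultured with uncultured aged HSPCs shows what differed between cultured and uncultured aged cells, with any difference in when the groups were prepared. All interferon-stimulated and cholesterol synthesis genes measured and most megakaryocyte (17 of 18) and monocyte genes (14 of 21) were higher after culture. All B lineage genes and most immediate early (22 of 23) and erythroid genes (16 of 20) were lower. Oasl2, an interferon-induced gene, was at 10.6 ± 0.248 CPM in uncultured and 479 ± 6.02 CPM in vehicle-cultured cells, and Fosb at 2844 ± 70.2 and 32.1 ± 1.35 CPM. The share of counts in immunoglobulin genes went from 19.8% to 0.841%. edgeR called 5903 genes higher and 5845 lower after culture (70.5% of those tested), and 1938 and 2863 of them changed by at least 1 on the log2 scale. The libraries of both groups did not overlap for 11929 genes (71.5%), where chance gives 10%. Camera (limma) called 8 lists higher and 9 lower. The smallest limma camera adjusted p of any list was 8.95e-07 with an estimated correlation, so smaller values below rest on the preset correlation.

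All 30 interferon-stimulated genes rose (median 4.26, limma camera adjusted p = 1.07e-104). Irf7, a transcription factor of the interferon response, went from 23.0 ± 2.43 to 558 ± 8.24 CPM and Ifit2 from 15.1 ± 0.353 to 325 ± 3.43 CPM. All 22 genes of cholesterol synthesis rose (median 2.50, limma camera adjusted p = 5.82e-32). Sqle went from 24.4 ± 2.04 to 204 ± 5.08 CPM and Hmgcs1 from 20.6 ± 2.63 to 251 ± 2.04 CPM. Of 18 megakaryocyte and platelet genes 17 rose and 1 was not called (median 3.20, limma camera adjusted p = 8.15e-21; 18 rose when adjusted over the list alone). Pf4 rose by 4.99, Vwf by 3.14 and Itga2b by 3.02 on the log2 scale. Monocyte and macrophage genes gave 14 higher and 7 lower (median 1.58, limma camera adjusted p = 8.05e-13), among them Lyz2 (140.0 ± 2.18 to 2768 ± 21.96 CPM), Mpeg1 (132 ± 9.37 to 744 ± 9.20 CPM) and Csf1r, the receptor of macrophage colony-stimulating factor (76.2 ± 2.62 to 409 ± 3.67 CPM).

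Every measured G2 and M phase gene was higher after culture (25 of 25, median 0.68, limma camera adjusted p = 4.97e-05), as were 25 of 28 S phase genes, with 2 lower and 1 not called (median 0.42, limma camera adjusted p = 0.00322). Mki67 and Cenpe rose by 0.77 and 1.22. Fatty acid genes gave 14 higher, 3 lower and 2 not called (median 0.75, limma camera adjusted p = 1.14e-05). The lipid droplet protein Plin2 and fatty acid synthase Fasn rose by 2.64 and 1.48, whereas the desaturase Scd1 fell by 2.70. Antioxidant genes gave 15 higher, 5 lower and 5 not called (median 0.33, limma camera adjusted p = 6.27e-04), with Slc7a11 at 0.752 ± 0.0173 and 44.7 ± 0.760 CPM and Nfe2l2, the NRF2 transcription factor, at 57.4 ± 5.81 and 203 ± 3.55 CPM.

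Of 23 immediate early genes 22 fell and 1 rose (median -3.15, limma camera adjusted p = 1.55e-104). Fos (2272 ± 23.2 to 60.9 ± 3.32 CPM), Jun (2297 ± 30.1 to 88.7 ± 4.93 CPM) and Nr4a1 (1078 ± 12.6 to 7.42 ± 0.537 CPM) were among the most abundant. All 16 B lineage genes fell (median -4.76, limma camera adjusted p = 7.34e-59), such as Cd79a (698 ± 24.6 to 13.3 ± 1.26 CPM) and Cd74 (4113 ± 112 to 396 ± 1.79 CPM). Of 20 erythroid genes 16 fell, 3 rose and 1 was not called (median -4.14, limma camera adjusted p = 1.14e-05), with Car1 at 78.5 ± 1.16 and 0.165 ± 0.0574 CPM. Genes of T and natural killer cells gave 14 lower, 1 higher and 2 not called (median -3.63, limma camera adjusted p = 0.00322; 2 rose when adjusted over the list alone). Cd2 fell by 6.82 and Il2rb by 3.17, while Ccl5, a chemokine that other cells also make, rose by 1.19. Granulocyte progenitor genes gave 12 lower and 3 higher (median -1.39, limma camera adjusted p = 1.92e-08), with Elane at 2795 ± 72.7 and 518 ± 2.78 CPM and Mpo at 7254 ± 182 and 2171 ± 45.8 CPM. Unfolded protein response genes gave 15 lower, 1 higher and 4 not called (median -0.61, limma camera adjusted p = 6.36e-08; 16 fell when adjusted over the list alone), including Herpud1 and Xbp1, which fell by 2.78 and 1.96. Histone genes, uncertain as above, gave 11 lower and 3 not called (median -1.60, limma camera adjusted p = 0.0109).

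ERK target genes went both ways (12 rose and 10 fell), with a median of 0.35, a mean of -0.43 and a limma camera call down (adjusted p = 0.00120) that was lost without the low-count filter (adjusted p = 0.577). Dusp1 and Egr1 fell by 3.56 and 3.35. Lymphoid-primed progenitor genes (5 rose, 8 fell and 3 were not called; median -0.02) were called down (limma camera adjusted p = 0.00869), with adjusted p = 0.0990 with an estimated correlation. With single libraries left out their median ran from -0.16 to 0.0017. Without the low-count filter it was 6.07e-03 and the limma camera adjusted p was 0.322. Mature neutrophil genes (10 fell, 4 rose and 1 was not called; median -0.90) were not called, at a limma camera adjusted p of 0.0607, with Ngp lower (log2 fold change -1.94) and the collagenase Mmp8 higher (log2 fold change 4.84). Stroma genes (9 fell and 3 rose) had a median of -2.98, or -1.54 with genes near 0 counts at their bounds, and were not called (limma camera adjusted p = 0.235). Pyrimidine metabolism was not called either (13 rose, 12 fell and 4 were not called; median -0.01, mean -0.08, test direction up, limma camera adjusted p = 0.353), with Cmpk2 at 14.5 ± 1.24 and 207 ± 6.38 CPM. The other lists described here after culture had the same member counts when adjusted over the list alone.

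Among the genes that changed most after culture were Saa3, a serum amyloid protein (0.276 ± 0.187 to 356 ± 10.1 CPM), the serotonin transporter Slc6a4 (0.116 ± 0.106 to 151 ± 2.98 CPM) and Acod1, the itaconate-producing enzyme of activated macrophages (0.478 ± 0.0677 to 289.8 ± 3.23 CPM). Mmp12 and Ccl7 had 0 counts in the uncultured aged libraries and were at least 255-fold and 199-fold higher after culture, against a floor of 3 counts over the group. Among genes that fell, Ctla4 (152 ± 6.19 to 0.579 ± 0.172 CPM) and the B cell scaffold Bank1 (97.2 ± 5.43 to 0.748 ± 0.236 CPM) ranked with Nr4a1. Ermap, with 2 counts over the vehicle libraries, was lower by a ratio of 771 (counting interval 213 to 6370).

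**Figure D4:**
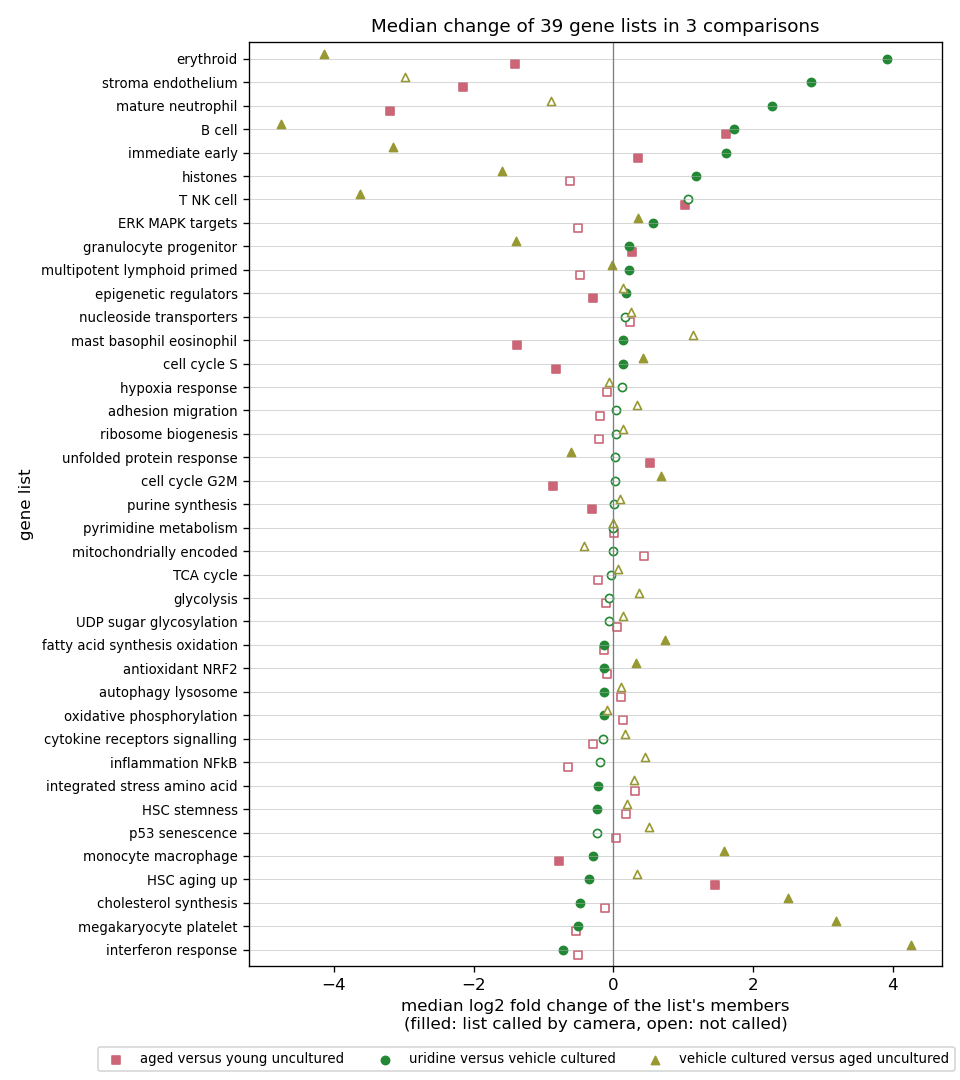
Median log2 fold change of the measured members of each of the 39 gene lists in the comparisons of aged with young, uridine with vehicle and vehicle-cultured with uncultured aged cells; filled symbols mark lists called by camera at an adjusted p under 0.05. Interferon-stimulated genes stood at -0.51, -0.72 and 4.26, and immediate early genes at 0.36, 1.62 and -3.15.

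Whether genes that differ with age moved the other way with uridine was asked on the calls of the first and second comparisons, which share no library. However, the uridine libraries lay near a mixture of vehicle and young levels, as given above. If young RNA is in them, the young level enters both comparisons with opposite signs, and part of the overlap follows from that. Most mature neutrophil genes (13 of 15), all of which were lower in aged cells, and the collagen genes Col1a1 and Col1a2 were higher with uridine: S100a9, for example, was at 1266 ± 52.7 CPM in young, 199.0 ± 9.49 in aged, 107 ± 3.42 in vehicle and 516 ± 13.0 CPM in uridine libraries. Of the 5354 genes lower in aged cells, 2036 (38.0%) were higher with uridine, where independent lists would share 1073 (odds ratio 4.71). Of the 5535 genes higher in aged cells, 1495 (27.0%) were lower with uridine, where independent lists would share 1002 (odds ratio 2.34, Fisher's exact test, two-sided, p = 3.06e-94). Genes called in the same direction were fewer than for independent lists, at 648 higher in both against 1109 (Fisher's exact p = 9.76e-86) and 757 lower in both against 969 (Fisher's exact p = 1.70e-20). Genes are not independent replicates, so these p-values describe the overlap across genes only.

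Across all genes, the fold changes of both comparisons were related by a Pearson r of -0.276 and a Spearman rho of -0.289. As a set, the genes higher in aged cells had a median log2 fold change of -0.10 with uridine (limma camera adjusted p = 0.00130), and those lower in aged cells a median of 0.10 (limma camera adjusted p = 9.53e-06). Restricted to age changes of at least 1 on the log2 scale, the first set was not called (median -0.12, limma camera adjusted p = 0.0544), whereas the second had a median of 0.58 (limma camera adjusted p = 1.37e-11). After the same subtraction of the young-like fraction the medians were -0.07 and 0.04, from -0.09 and 0.10 on the same log2(CPM + 0.5) scale.

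Genes that moved the same way in both comparisons included the kinase Sik1 (249.7 ± 6.80, 675 ± 7.94, 12.9 ± 0.572 and 95.8 ± 1.83 CPM in young, aged, vehicle and uridine libraries). It was higher in aged than in young cells and higher with uridine than with vehicle, as were Nr4a1, Jund, Junb and Tsc22d3. Lyz2 was lower in both (995 ± 34.7, 140.0 ± 2.18, 2768 ± 21.96 and 1793 ± 27.3 CPM). Among the genes that moved in opposite directions were Ngp, Ltf, Camp, Col1a1, S100a8, Dntt and Cd177, each lower with age and higher with uridine, and Jchain, which was higher with age and lower with uridine.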

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

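No call that was tested again under an alternative changed direction, and the cause of the differences below was not tested. With a log2 fold change of at least 1, 2105 genes were higher and 1508 lower in aged cells (5535 and 5354 without it), 1054 higher and 118 lower with uridine (3342 and 3018), and 1938 higher and 2863 lower after culture (5903 and 5845). Asked to be called in the same direction against young cells as well, 134 higher and 196 lower genes remained with uridine. The genes higher with age had a median log2 fold change of -0.10 with uridine, and -0.12 with age changes of at least 1 (limma camera adjusted p = 0.0544); those lower with age had 0.10, and 0.58 with age changes of at least 1 (limma camera adjusted p = 1.37e-11). After the young-like fraction was subtracted, the medians of the sets higher and lower with age were -0.0671 and 0.0449. This subtraction gave no new test of genes or lists. With levels below 0 set to 0, most list medians with uridine shrank or changed sign under it, such as mature neutrophil genes from 2.13 to -0.01, erythroid from 3.16 to -0.10 and B lineage from 1.49 to -0.52. Genes of these example lists helped to set the fraction, so their loss was in part fixed in advance. These last alternatives on young cells were chosen after seeing the data. Leaving out each library in turn gave 5233 to 5359 genes higher and 5157 to 5276 lower in aged cells, 2880 to 2995 and 2536 to 2662 with uridine, 5699 to 5848 and 5673 to 5763 after culture, and medians of -0.11 to -0.10 and 0.10 to 0.11 for the age sets. DESeq2 called 3160 genes higher and 3439 lower with uridine.

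The replicate numbers do not pair the libraries: deviations of libraries with the same number correlated between -0.0400 and 0.0235 (18 pairs), and those with different numbers between -0.0331 and 0.0348 (36 pairs). With the number as a block, 5450 and 5318 genes were called with age, 3289 and 2961 with uridine and 5882 and 5785 after culture, with medians of -0.10 and 0.0994 for the age sets.

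Among named genes and lists, calls lost beyond those given with the results were Dsg2 with age without aged replicate 3 (edgeR adjusted p = 0.105), and Tk1 with age in 5 settings, up to an edgeR adjusted p of 0.344. With uridine they were Sult1a1 in 7 settings, up to an edgeR adjusted p of 0.162, Amotl2 in 8, up to 0.145, Alcam (0.0682) and Cmpk1 (0.0868). After culture they were Trpc1, Ghr and Ddr1, up to an edgeR adjusted p of 0.0896, and Uck2 (0.307 with upper-quartile factors).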

Other observations

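The tests of mixing with young cells and of plasma cell transcripts were chosen only after the results were seen, whereas the bounds of the immunoglobulin scaling test and of the regrouping of libraries were written before their results.

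The uridine libraries may contain RNA of uncultured young cells. Of genes far higher in young than in vehicle libraries, 93.1% lay within 0.1 of a common fraction of the gap, 0.333. They included neutrophil, B lineage, erythroid and immediate early genes, and a mixture of RNA would give such a pattern. In simulated mixtures at true fractions of 0.3 and 0.5, 98 and 98.7% lay within 0.1, so the observed spread was somewhat wider. The simulation took the young and vehicle means as exact. RNA like that of the uncultured aged libraries was excluded as a source, since 270 genes high only in them lay at a median fraction of -8.52e-04. Without immunoglobulin genes and Jchain, the median of the remaining 121 was 0.00417. Many of the 270 mark plasma or B cells, such as Sdc1 and Cd22, so aged RNA without such cells was not tested. A shift of the cultured cells themselves by a common fraction cannot be separated from mixing: the medians of the lists with at least 5 such genes differed by 0.0275, with 3 stroma genes lower, at 0.279, and 1 histone gene at 0.471, and no bound follows from that. Over 11070 genes with a mean of at least 5 CPM, the SD of the log2 ratio of uridine to vehicle was 0.451. Against a mixture of young and vehicle levels at the fraction of 0.333 it was 0.138. Of these genes 90 lay off that mixture by log2 0.5 or more. The fraction came from these same libraries. If mixing holds, much of the whole difference between uridine and vehicle may not be an effect of uridine. This includes the rise of markers such as Ltf, Slc4a1 and Col1a1. The same holds for the part of the opposite movement with age that subtraction removed (medians -0.09 and 0.10 before, -0.07 and 0.04 after). A fresh pair of cultures, with young and aged cells that carry different genetic marks, could decide it.

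Mixing with young RNA at 1 common share does not account for the size of the fall with uridine of 181 genes at least 10 times higher in vehicle than in young libraries, as a group. Their fall corresponds to a share of 0.419 of the gap to young cells, which is 0.0858 more than the share of the rise of young-high genes. It was 0.0820, 0.0915 and 0.0753 more in the single uridine libraries, and a scaling error of -0.13 on the log2 scale would be needed to make them equal, where 1936 genes alike in vehicle and young libraries had a median of -0.02. After subtraction of the young-like fraction, the median log2 change went from -0.71 to -0.19 for interferon-stimulated genes, from -0.48 to 0.0022 for cholesterol synthesis genes and from -0.46 to 0.01 for genes higher in old stem cells, while oxidative phosphorylation genes were at -0.19. A weighted regression over all genes tested, on CPM without TMM factors, gave a young share of 0.382, and a larger share leaves less of the interferon fall, so whether uridine lowers these genes stays open.

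The uncultured aged libraries may include plasma cells, which the label of stem and progenitor cells and a sort for them would exclude. From a list of 20 plasma cell genes other than immunoglobulin genes, 95% were higher in aged than in young cells (19 of 20, median log2 fold change 2.33, with 4 of the 20 also in the fixed lists), as in Sdc1 (22.6 to 287 CPM), Prdm1 (4.45 to 133 CPM), Txndc5 (201 to 1632 CPM) and Tnfrsf17 (0.640 to 30.2 CPM). The list and the 4 genes given here were chosen after their values were seen, so the 95% describes these libraries and is no independent test. Of all 16675 genes tested, 5535 were higher in aged cells. All 20 plasma cell genes were also detected in young cells, and 217 of 221 immunoglobulin genes were higher in aged cells too. Leaving out immunoglobulin genes and Jchain before scaling changed the counts of called genes with age by a ratio of 1.017 at most. Those genes are themselves among the calls, so this ratio is a coarse measure. The median log2 fold change of the genes tested was 0.0172 with them and 0.0189 without them. A large distortion of the scaling by immunoglobulin reads was therefore not seen. The rise of unfolded protein response and B cell genes with age may then reflect cell composition and not a change within stem cells. After culture, all of the 20 genes but Cd28 (38.3 to 54.5 CPM) had lower means than in uncultured aged cells, such as Sdc1 (287 to 21.4 CPM). The fall of unfolded protein response and B cell genes after culture therefore has the same limit. Cell composition was not measured. The other lists that differed with age, such as neutrophil, erythroid, basophil, stroma, cell cycle and stem cell ageing genes, cannot be assigned to changes within stem cells either.

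Regrouping the 6 libraries of each comparison gave 10 splits, too few for a share under 0.05. Only 1 split of 10, the real one, called as many genes in each comparison: 10301 with age, 6782 with uridine and 11198 after culture by edgeR on 6 libraries, against at most 0 in any other split. Every other split puts libraries of both groups on each side, so the group difference adds to the spread there. The 0 calls therefore cannot show how many calls arise without a group difference. At an unadjusted p under 0.05, edgeR counted at most 107, 197 and 60 genes in the other splits.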
